A study of Mus musculus with 9 samples.

How the data were processed

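Monocytes were sorted by flow cytometry from 6-week-old C57Bl6 Cx3cr1gfp/+ mice as CD11b-positive, F4/80-low, Gr1-negative, fluorescent cells that lacked NK1.1, CD3 and B220, per the labels. The mice were uninfected (blood) or had received 10000 bacteria of the Listeria monocytogenes strain EGDe into the peritoneal cavity 2 h or 8 h before (peritoneal lavage), with 3 mice per group and 1000 cells per mouse. The messenger RNA was amplified by a global PCR protocol whose details the labels call undisclosed, and 250 ng of cDNA were labelled with Cy3 and hybridized to 1-colour whole mouse genome arrays, per the labels' protocols. Amplification from so few cells can distort low signals, and no array measured the same cells in repeat.

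The scanner output holds the processed signal of each spot as an intensity, made by Agilent Feature Extraction 9.1.3.1 with background subtraction, detrending within the array and surrogate values for dim spots, per the file headers. No normalization between arrays is recorded in them. The deposited value table holds a ratio, the processed signal divided by its array's median, as tested on the values. Each array had 43379 non-control spots and 41174 distinct probes, of which 245 were spotted 10 times. In the file of blood replicate 1 the values carry 3 significant digits and 27 gene names had been altered, so names were taken from the other arrays. On 8 h replicate 2, 2 spots were broken and treated as missing. Probes took their gene symbol from the RefSeq accession on the array (22951 probes), the symbol itself (6659) or a synonym (3109), and 8455 kept the name in the files. No coordinates are given, because the files name no genome build.

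From these intensities, the log2 of the processed signal minus the array's 75th percentile was computed, after signals of 0 or less were set to the array's lowest positive signal and outlier-flagged spots were set to missing (2380 spots over the 9 arrays). A probe was kept if well above background on at least 2 of the 3 arrays of at least 1 group (36831 probes). Another 248 probes flagged as outliers on 3 or more arrays were left out, which left 36583 probes or 88.9%. Spots of a probe were averaged, and the brightest kept probe stood for each of 24854 genes, 7980 of which had several. Kept probes of the same gene were called in opposite directions for 5 genes at 2 h against blood, for 1 at 8 h against blood and for 0 between 8 h and 2 h.

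The groups were compared with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 9 arrays, eBayes, two-sided tests and Benjamini-Hochberg adjustment over the genes tested, and a threshold of 0.05. A moderated F test covered the 3 groups. An at-least fold was taken against the lowest signal well above background where every array of the dimmer group was below background. For named genes with 1 or 2 such arrays above background, the difference was also computed with the other arrays set to that signal. Gene lists were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over 34 lists in each comparison, and again with an estimated correlation. Camera sets a list's genes against all other genes, so a list called higher or lower is so relative to them. It took only genes with a value on every array, so 709 genes, among them Retnla and Relb, did not enter it. The counts and medians of lists given beside camera values include such genes. In Python 3.11.15, tables were handled with pandas 2.3.3 and numpy 2.4.6 and plots drawn with matplotlib 3.10.9.

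Before the data were examined, the groups, the tests, the alternatives not named below as added, the gene lists and the rule for named genes were fixed. The lists were written from general knowledge of monocytes, macrophages and infection, with some knowledge of the study's themes, so they are not blind to it. They comprise 22 programmes (inflammatory cytokines, chemokines, NF-kappaB pathway and feedback, pattern recognition, interferon response, microbial killing, complement, macrophage differentiation, alternative activation, tissue remodelling and growth factors, antigen presentation and costimulation, immediate early and stress response, feedback inhibitors of inflammation, hypoxia and glycolysis, oxidative stress and metallothioneins, cholesterol and lipid handling, cell cycle, migration and adhesion receptors, apoptosis regulators, Gr1-negative blood monocyte genes, ribosomal proteins, mitochondrial respiration) and markers of 12 other cell types. Of 683 distinct genes listed, 670 had a probe. Of the list memberships that were not tested, 14 had no probe so named, 13 were below the filter and 9 were outlier-flagged, among them Nfkbia, F13a1 and Rpl3. Named genes were, per comparison, the 5 called genes with the largest increase and decrease that had an official-style symbol, a signal above background in each group and no overlap between the groups' arrays. They further included the 2 called genes with the largest at-least fold in each direction, up to 3 called members of each list described (or its member with the smallest p where fewer than 2 were called), and 17 genes fixed in advance.

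The method was tested on simulated data built on the real arrays' levels and spread, with 200 of 24854 genes changed. For 2 h against blood, 4%, 54%, 74% and 90% of genes changed by 1, 2, 3 and 5 (log2) were recovered, with 10 calls among unchanged genes. For 8 h against blood, 10%, 52%, 68% and 90% were recovered, with 6 calls among unchanged genes. Genes changed by 2-fold were therefore mostly missed in the simulation. Far fewer genes were called there than in the data, and the adjustment is stricter with fewer calls, so these shares need not hold for the data.

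The alternatives covered quantile normalization, 2 other scalings, normexp background correction with an offset of 50, the deposited value table, 2 other filters, the mean of a gene's probes, fits of only the 6 arrays compared, the replicate number, slide and scan day as blocks, a mean-variance trend, array weights, a fold threshold, an estimated inter-gene correlation and each array left out. The normexp fit without the lowest 0.1% of spots and the fit with outlier-flagged spots kept were added after the data were seen. Scan day stands here for the day of image extraction given in the file headers, since the date of scanning was not read. Slide as a fixed block leaves no comparison with blood, since all blood arrays share a slide, and for 8 h against 2 h it is the same model as the scan-day block.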

Results

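Gene expression was measured in Gr1-negative monocytes sorted from mice that carry a green fluorescent protein gene in place of a copy of Cx3cr1, the fractalkine receptor gene. The cells came from the blood of uninfected mice, or from the peritoneal cavity 2 h or 8 h after intraperitoneal injection of Listeria monocytogenes, a bacterium that lives inside host cells. Each of the 3 groups held 3 one-colour arrays with 1000 sorted cells behind each array, and no uninfected peritoneal cells were analysed here. The number of arrays limits the precision of every value below.

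Between 80.2% and 90.2% of the non-control spots were well above background, and the median spot was 13.4 to 17.7 times as bright as its local background. Across genes, which are not independent replicates, the correlation of log2 signals was 0.905 to 0.922 between blood arrays, 0.946 to 0.955 between 2 h arrays and 0.944 to 0.960 between 8 h arrays. Arrays at 2 h and 8 h correlated at 0.924 to 0.955, and blood with peritoneal arrays at 0.881 to 0.910. The first principal component held 31.6% of the variance and put the blood arrays at -111 to -78.7 and the peritoneal arrays at 31.3 to 56.8. The median standard deviation of a gene was 0.45 (log2) in blood, 0.31 at 2 h and 0.31 at 8 h. Of 24854 genes tested, 925 differed among the 3 groups (limma F test, adjusted p under 0.05). Without 2 h replicate 1, 2 or 3 the count was 483, 487 and 552, without 8 h replicate 1, 2 or 3 it was 521, 404 and 566, without blood replicate 2 it was 430, and with scan day as a block 205. The 3 blood arrays shared slide 1, 2 h replicates 1 and 2 shared slide 2, and 2 h replicate 3 shared slide 3 with the 8 h arrays. By the image extraction times in the file headers, which define the scan day here, slides 1 and 2 belonged to day 1 and slide 3 to day 2. Below, values are log2 differences ± standard error, with n = 3 arrays per group unless another number is given, and called genes and lists have an adjusted p under 0.05 from limma.

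The first comparison asks how these cells differ between the circulation and the infected peritoneal cavity 2 h after injection, where tissue and infection change together. Retnla, a marker of alternatively activated macrophages, was 1049-fold higher than in blood (10.04 ± 0.33, n = 2 arrays at 2 h, adjusted p = 0.000143). Plau, the urokinase plasminogen activator, was 177-fold higher (7.47 ± 0.41, adjusted p = 0.00037, above background on 2 of 3 blood arrays) and C1qc, a chain of the complement initiator C1q, 175-fold higher (7.45 ± 0.50, adjusted p = 0.000632). In the other direction, S1pr5, a sphingosine-1-phosphate receptor that steers exit of cells from the bone marrow into blood, fell by 4.88 ± 0.52 (29.4-fold, adjusted p = 0.00336), and Nr4a1, the nuclear receptor needed for Gr1-negative monocytes to develop, fell by 3.41 ± 0.20 (adjusted p = 0.00041). In total 740 genes were higher and 575 lower at 2 h, 680 and 551 of them by at least 2-fold. Under quantile normalization the balance turned, with 712 higher and 740 lower. At an unadjusted p under 0.05 the counts were 3487 and 2139. The median over all genes was 0.13, and ranged from 0.05 under quantile normalization to 0.31 under normexp background correction.

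Among the gene lists, tissue remodelling and growth factors rose at 2 h (11 of 32 tested genes higher, 0 lower, 21 not called, camera adjusted p = 2.4e-07). Remodelling genes adjusted over the list alone numbered 13 higher and 0 lower, and the list had an adjusted p = 0.103 with an estimated correlation. Vcan, a matrix proteoglycan, gained 4.35 ± 0.32 by its brightest probe, while its other 3 kept probes differed by 0.0065, 1.90 and 1.94. Complement genes rose (6 of 19 higher, 0 lower, 13 not called, camera adjusted p = 1.2e-05), with C1qa at 4.97 ± 0.26 and C1qb at 4.25 ± 0.26. For complement, 11 were higher and 0 lower adjusted over the list alone, with an adjusted p = 0.103 with an estimated correlation. Antigen presentation and costimulation genes rose (9 of 21 higher, 1 lower, 11 not called, camera adjusted p = 2.6e-05). Of these, 12 were higher and 2 lower adjusted over the list alone, and the list had an adjusted p = 0.0684 with an estimated correlation. They included H2-DMb1, which helps load peptides on class II molecules (2.87 ± 0.23), and Ciita, the master regulator of class II genes (3.27 ± 0.48). Chemokines rose (7 of 24 higher, 0 lower, 17 not called, camera adjusted p = 0.000117). Chemokine genes adjusted over the list alone numbered 12 higher and 1 lower, and adjusted p = 0.120 with an estimated correlation. Cxcl16, a membrane-bound chemokine, was 48.8-fold higher (5.61 ± 0.38). Ccl12, a ligand of Ccr2, was 5.99 ± 0.47 higher, but above background on only 1 of 3 blood arrays, and 53.2-fold higher with the others set to the lowest signal above background. Cxcl10, an interferon-inducible chemokine, was 6.58 ± 1.11 higher (adjusted p = 0.0184, 5.83 with the dim 1 of 3 blood arrays set to the lowest signal above background), a call lost without any 1 of 2 h replicates 1, 2 and 3, where the adjusted p reached 0.0611.

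The alternative activation list rose as well (9 of 22 higher, 2 lower, 11 not called, camera adjusted p = 0.0267). Alternative activation genes adjusted over the list alone numbered 11 higher and 4 lower, and adjusted p = 0.349 with an estimated correlation. Mgl2, a galactose-binding lectin, rose by 3.90 ± 0.24. Beside these lists, markers of resident peritoneal macrophages were not called as a list at 2 h (1 of 17 higher, 1 lower, camera adjusted p = 0.975) or at 8 h (1 of 17 higher, 0 lower, camera adjusted p = 0.893). Their counts adjusted over the list alone were 5 higher and 3 lower at 2 h, and 2 and 2 at 8 h. Macrophage differentiation genes rose (5 of 25 higher, 0 lower, 20 not called, camera adjusted p = 0.0113), led by Axl, a receptor for apoptotic cells (3.81 ± 0.34). The NF-kappaB pathway and feedback list rose (5 of 25 higher, 0 lower, 20 not called, camera adjusted p = 0.0113), with Icam1, an adhesion molecule, at 3.61 ± 0.39 by its brightest probe. The other kept probe of Icam1 differed by 2.15 and was not called by limma over probes (adjusted p = 0.0708). In each of these last lists, 7 genes were higher and 1 lower adjusted over the list alone, and adjusted p = 0.424 with an estimated correlation. The camera call ended without blood replicate 1 or 2 h replicate 3 for the NF-kappaB list, without blood replicate 1 or 2 h replicate 1 for macrophage differentiation, and without blood replicate 1 for alternative activation, where adjusted p reached 0.148, 0.126 and 0.205. The NF-kappaB call also ended with scan day as a block (median 0.37 in place of 0.46, adjusted p = 0.0675), and the alternative activation call with the replicate number as a block (adjusted p = 0.0551). In the list of inflammatory cytokines, 1 of 24 genes was higher and 0 lower (5 and 0 adjusted over the list alone, camera adjusted p = 0.0989). That gene was Il1rn, the interleukin-1 receptor antagonist, which rose by 4.72 ± 0.52. Il1b differed by 1.20 ± 0.30 (adjusted p = 0.0608) and Tnf by 1.20 ± 0.69 (adjusted p = 0.342), and neither was called.

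The Gr1-negative blood monocyte list fell at 2 h, with 11 of 22 genes lower, 0 higher and 11 not called (camera adjusted p = 4.3e-12). Adjusted over the list alone 13 were lower and 0 higher, and adjusted p = 0.0684 with an estimated correlation. Slc12a2, an ion cotransporter, fell by 3.65 ± 0.39. Pglyrp1, a peptidoglycan-binding protein, fell by 3.93 ± 0.45. Cx3cr1, whose locus carries the reporter, differed by -0.34 ± 0.35 (adjusted p = 0.617). Beside this fall, red cell genes fell as a list, with 0 of 11 called by limma and 0 higher and 6 lower at an unadjusted p under 0.05 (camera adjusted p = 0.00523). Red cell genes adjusted over the list alone numbered 0 higher and 4 lower, and adjusted p = 0.103 with an estimated correlation.

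Another 5 lists were called at 2 h with adjusted p between 0.0429 and 0.0465, and each of these calls ended when each array's median replaced its 75th percentile. Cell cycle genes rose, with 2 of 24 higher and 0 lower (6 and 0 adjusted over the list alone, adjusted p = 0.195 with an estimated correlation). Ribosomal protein genes rose, with 0 of 34 called by limma and 4 higher and 0 lower at an unadjusted p under 0.05 (0 and 0 adjusted over the list alone, adjusted p = 0.810 with an estimated correlation). Interferon response genes fell, with 0 of 39 higher and 1 lower (0 and 0 adjusted over the list alone, adjusted p = 0.794 with an estimated correlation). Migration and adhesion receptor genes fell, with 4 of 27 higher and 5 lower (5 and 8 adjusted over the list alone, adjusted p = 0.424 with an estimated correlation). NK cell genes fell, with 1 of 13 higher and 1 lower (1 and 4 adjusted over the list alone, adjusted p = 0.364 with an estimated correlation). The cell cycle call ended without blood replicate 1, 2 h replicate 2 or 3 or 8 h replicate 3 (adjusted p up to 0.205), and the ribosomal call without blood replicate 1 or 2, 2 h replicate 1 or 8 h replicate 3 (up to 0.631). The interferon call ended without blood replicate 3, 2 h replicate 3 or 8 h replicate 3 (up to 0.996), the migration call without blood replicate 2 or 3, 2 h replicate 1 or 8 h replicate 3 (up to 0.373), and the NK cell call without blood replicate 2, any 1 of the 2 h arrays, or 8 h replicate 2 or 3 (up to 0.290). With scan day as a block the cell cycle, interferon and NK cell calls ended (adjusted p = 0.0515, 0.327 and 0.0675), with medians of 0.63, -0.18 and -0.30 in place of 0.55, -0.34 and -0.38.

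Single genes selected by the naming rule at 2 h also included Cysltr1, a leukotriene receptor, which was 6.24 ± 0.73 higher, and Arrdc3, an arrestin family member, which fell by 6.50 ± 1.05. The other kept probe of Cysltr1 differed by 3.04 and was not called by limma over probes (adjusted p = 0.0988). Against signals below background in blood, Tmem273 was at least 36.0-fold higher and Tarm1 at least 32.5-fold higher. Against signals below background at 2 h, Ypel2 was at least 14.1-fold lower and Abcb1a, a drug efflux pump, at least 10.4-fold lower. Thbd, the thrombin receptor thrombomodulin, fell by 6.27 ± 1.04, Gzma and Gzmb, proteases of cytotoxic granules, fell by 5.84 ± 0.98 and 4.95 ± 0.97, and Mrc1, the mannose receptor, rose by 6.18 ± 1.43. These differences rest on signals mostly at background: Thbd, Gzma and Gzmb were above background on 1 of 3 arrays at 2 h, and Cysltr1 and Mrc1 on 1 of 3 in blood. With the arrays below background set to the lowest signal above it, the differences were -6.19 (Thbd), -5.42 (Gzma), -4.29 (Gzmb), 4.88 (Cysltr1) and 5.44 (Mrc1), while Arrdc3, above background on 2 of 3 arrays at 2 h, differed by -5.85. The call of Thbd ended without 2 h replicate 1 or 3 (adjusted p up to 0.0632), that of Gzma without blood replicate 2 or 2 h replicate 1 or 2 (up to 0.0624), and that of Tarm1 without any 1 of the 6 blood and 2 h arrays (up to 0.0851). Those of Gzmb and Ypel2 ended without blood replicate 1 or 2, any 1 of the 2 h arrays or 8 h replicate 2 (up to 0.0906 and 0.0957), and that of Mrc1 without any 1 of the 9 arrays but blood replicate 3 (up to 0.130). Of the 64 named genes called at 2 h, 29 kept their call without each of the 9 arrays in turn, and 26 under every other alternative.

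Without 2 h replicate 1, 2 or 3, the genes called higher numbered 214, 219 and 280 and those lower 205, 264 and 321. Without blood replicate 2 they were 362 and 265, and without 8 h replicate 1 or 2, which enter through the shared spread, 485 and 361 were higher and, without 8 h replicate 2, 337 were lower. With scan day as a block, which compares blood only with 2 h replicates 1 and 2, 276 genes were higher and 318 lower, and 2782 and 1967 at an unadjusted p under 0.05. The median size of the difference over the called genes, which share most arrays with that fit, was 1.90 with the block and 1.88 without it, and the median standard error 0.35 and 0.32. In comparisons with blood, slide and group could not be separated, since all blood arrays were on slide 1.

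**Figure D1:**
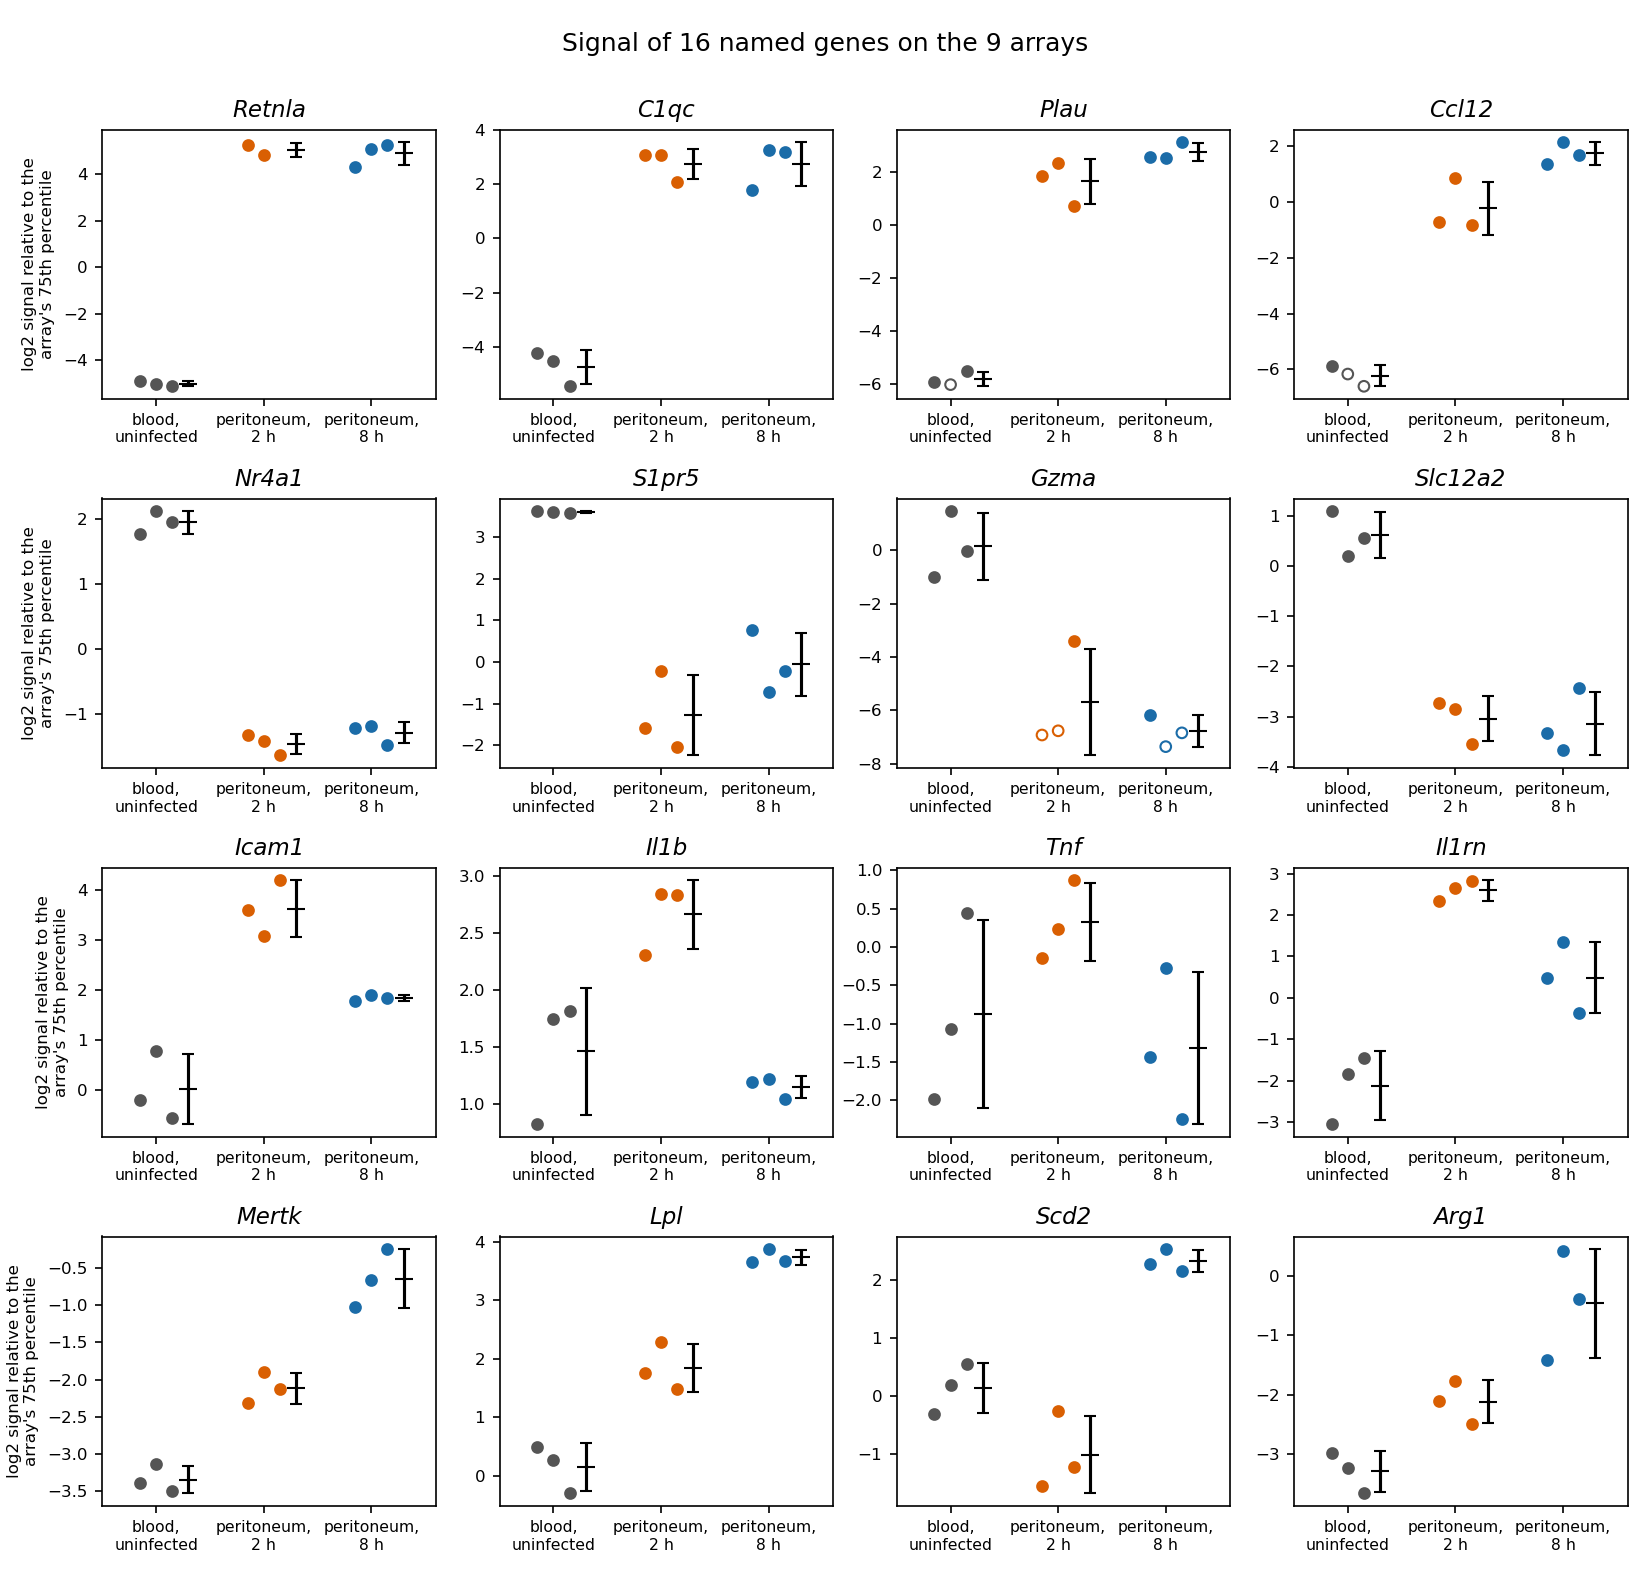
Log2 signal relative to each array's 75th percentile (y axis) for 16 genes in the 3 groups (x axis). Points are single arrays, open where the spot was not well above background, and bars give the mean ± standard deviation over n = 3 arrays (n = 2 for Retnla at 2 h); every Retnla, C1qc, Plau and Ccl12 point at 2 h and 8 h lies above every blood point, and every Nr4a1 and S1pr5 point lies below.

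The second comparison asks how the cells differ from blood 8 h after infection. Retnla was 948-fold higher (9.89 ± 0.29, adjusted p = 6.6e-05), Plau 380-fold higher (8.57 ± 0.41, adjusted p = 0.000139), and C1qc 175-fold higher (7.45 ± 0.50, adjusted p = 0.000608). Ccl12 was 7.96 ± 0.47 higher (adjusted p = 0.000387), but above background on only 1 of 3 blood arrays, and 209-fold higher with the others set to the lowest signal above background. Plau was above background on 2 of 3 blood arrays. Mirt1, a long noncoding RNA, fell by 6.25 ± 0.26 (adjusted p = 6.6e-05), Pdcd4, an inhibitor of translation, fell by 4.89 ± 0.32 (adjusted p = 0.000534) and Pglyrp1 fell by 4.64 ± 0.45 (adjusted p = 0.00232). In total 483 genes were higher and 360 lower, 472 and 352 of them by at least 2-fold, and 2436 and 2121 at an unadjusted p under 0.05. The median over all genes was -0.01.

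Tissue remodelling and growth factor genes rose at 8 h (12 of 32 higher, 0 lower, 20 not called, camera adjusted p = 4.0e-09). The counts adjusted over the list alone were 12 higher and 0 lower, and adjusted p = 0.0596 with an estimated correlation. Mmp12, the macrophage elastase, was at least 17.4-fold higher than in blood, where its signal was below background. Macrophage differentiation genes rose (5 of 25 higher, 0 lower, 20 not called, camera adjusted p = 0.000112). Of this list, 11 genes were higher and 1 lower adjusted over the list alone, and adjusted p = 0.217 with an estimated correlation. Axl stood at 4.73 ± 0.34, Lpl, the lipoprotein lipase, at 3.58 ± 0.29 and Mertk, a receptor for apoptotic cells, at 2.69 ± 0.25. Complement genes rose (5 of 19 higher, 0 lower, 14 not called, camera adjusted p = 0.00015), with 8 higher and 0 lower adjusted over the list alone and an adjusted p = 0.0999 with an estimated correlation. Antigen presentation and costimulation genes rose (5 of 21 higher, 0 lower, 16 not called, camera adjusted p = 0.00015), with 10 higher and 2 lower adjusted over the list alone and an adjusted p = 0.0596 with an estimated correlation. H2-DMb1 stood at 2.89 ± 0.23 above blood. Chemokines rose (6 of 24 higher, 1 lower, 17 not called, camera adjusted p = 0.000203), with 8 higher and 1 lower adjusted over the list alone and an adjusted p = 0.0999 with an estimated correlation. Cxcl16 was 17.2-fold higher (4.11 ± 0.38).

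Cholesterol and lipid handling genes, Lpl among them, rose at 8 h (6 of 22 higher, 0 lower, 16 not called, camera adjusted p = 0.000203). Lipid genes adjusted over the list alone numbered 11 higher and 3 lower, and adjusted p = 0.0596 with an estimated correlation. The alternative activation list rose (9 of 22 higher, 0 lower, 13 not called, camera adjusted p = 0.000813), with Mgl2 at 4.45 ± 0.24. It held 10 higher and 4 lower genes adjusted over the list alone, and adjusted p = 0.127 with an estimated correlation. Arg1, the arginine-degrading enzyme of alternatively activated macrophages, rose by 2.84 ± 0.45 (adjusted p = 0.0164, and 0.0587 without 8 h replicate 3). Cell cycle genes rose with 2 of 24 called higher and 0 lower (4 and 0 adjusted over the list alone, camera adjusted p = 0.00227, adjusted p = 0.0596 with an estimated correlation). Mitochondrial respiration genes rose with 0 of 28 called by limma and 5 higher and 0 lower at an unadjusted p under 0.05 (camera adjusted p = 0.0270). Mitochondrial genes adjusted over the list alone numbered 0 and 0, and adjusted p = 0.693 with an estimated correlation. That call ended without blood replicate 1 or 8 h replicate 2 or 3, where adjusted p reached 0.650, and with the mean of probes (0.0512). The inflammatory cytokine list was not called at 8 h (1 of 24 higher, 0 lower, 1 and 0 adjusted over the list alone, camera adjusted p = 0.830). The NF-kappaB list was not called either (1 of 25 higher, 1 lower, 3 and 2 adjusted over the list alone, camera adjusted p = 0.435), but with scan day as a block it was called lower (median -0.64, adjusted p = 0.00317). In it, Cd83, a maturation marker of antigen-presenting cells, fell by 2.87 ± 0.38.

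The Gr1-negative blood monocyte list fell again (11 of 22 lower, 0 higher, 11 not called, camera adjusted p = 1.5e-13). Adjusted over the list alone 15 were lower and 0 higher, and adjusted p = 0.0591 with an estimated correlation. Nr4a1 fell by 3.23 ± 0.20. Slc12a2 fell by 3.75 ± 0.39. Markers of other blood cells were lower beside it. Red cell genes fell (1 of 11 lower, 0 higher, camera adjusted p = 0.0018), with 6 lower and 0 higher adjusted over the list alone and an adjusted p = 0.0596 with an estimated correlation. T cell genes fell (2 of 19 lower, 0 higher, camera adjusted p = 0.00369), with 2 lower and 0 higher adjusted over the list alone and an adjusted p = 0.0608 with an estimated correlation. NK cell genes fell (2 of 13 lower, 0 higher, camera adjusted p = 0.00471), with 5 lower and 1 higher adjusted over the list alone and an adjusted p = 0.155 with an estimated correlation. The T cell call ended with scan day as a block (median -0.32 in place of -0.37, adjusted p = 0.0857), and the NK cell call had an adjusted p of 0.0773 without blood replicate 2. Cd3g, a chain of the T cell receptor complex, fell by 2.50 ± 0.25. Hba-a1, a haemoglobin chain, fell by 4.73 ± 0.80. Gzma fell by 6.93 ± 0.98 (adjusted p = 0.0120, and 0.0530 without 8 h replicate 2), above background on 1 of 3 arrays at 8 h, and differed by -6.42 with the others set to the lowest signal above background. Gzmb was at least 25.1-fold lower and Slc16a14, a transporter of the monocarboxylate family, at least 3.91-fold lower, with signals below background at 8 h.

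Tmem273 was at least 41.98-fold higher at 8 h than the lowest signal above background in blood. Mrc1 was 7.29 ± 1.43 higher (adjusted p = 0.0337) and above background on 1 of 3 blood arrays (6.55 with the others set to the lowest signal above background), a call that ended without any 1 of 8 of the 9 arrays, all but blood replicate 3 (adjusted p up to 0.117). The call of Hba-a1 ended without blood replicate 2 or 3 or any 1 of the 8 h arrays (adjusted p up to 0.0846). That of Gzmb ended without 8 h replicate 2 or 3 (up to 0.0682) and that of Slc16a14 without any 1 of the 8 h arrays (up to 0.080). Of the 58 named genes called at 8 h, 28 kept their call without each of the 9 arrays in turn, and 11 under every other alternative.

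Without 8 h replicate 1, 2 or 3, the genes called higher numbered 237, 139 and 205 and those lower 165, 103 and 160, and without blood replicate 2, 220 were lower. With scan day as a block, which ties the 8 h arrays to blood only through 2 h replicate 3, 16 genes were higher and 9 lower, and 1002 and 1067 at an unadjusted p under 0.05. The median size of the difference over the called genes, which share most arrays with that fit, was 2.19 with the block and 2.12 without it, while the median standard error was 0.58 in place of 0.34, so calls ended as the error grew. That block also called the ribosomal protein list higher (median 0.55, adjusted p = 0.000284).

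The calls at both times shared genes and directions. Of the genes called against blood, 316 were higher at both times, 245 were lower at both, and 0 were called in opposite directions by limma. Independent lists of these sizes would share 14.4 higher and 8.33 lower. Both comparisons use the same blood arrays, which favours the same sign. In 100 simulations, added after the data were seen, in which only the 2 h group differed from the shared blood arrays, by the measured means, a mean of 0.02 genes were higher and 0.02 lower in both. With no difference at 8 h built in, hardly any gene could be called there, so these shared counts had to be small. They do not tell how far the calls would overlap if both times differed from blood. These simulations called a mean of 3898 genes at 2 h, more than the 1315 of the data. The 1315 simulated genes with the smallest p had the same sign at 8 h in 64.1% of cases (63.8% of all those called), against 98.3% of the 1315 called in the data. The simulated noise was independent between arrays and held no slide effect. The blood arrays shared a slide with no peritoneal array, so an offset of that slide could also give shared calls and signs. The simulations cannot tell such an offset from a shared change in the cells. The shared 561 genes numbered 275 to 282 without 2 h replicate 1 or 2 or 8 h replicate 1, 344 without 2 h replicate 3, 358 without blood replicate 2, 187 without 8 h replicate 2, 298 without 8 h replicate 3 and 25 with scan day as a block.

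**Figure D2:**
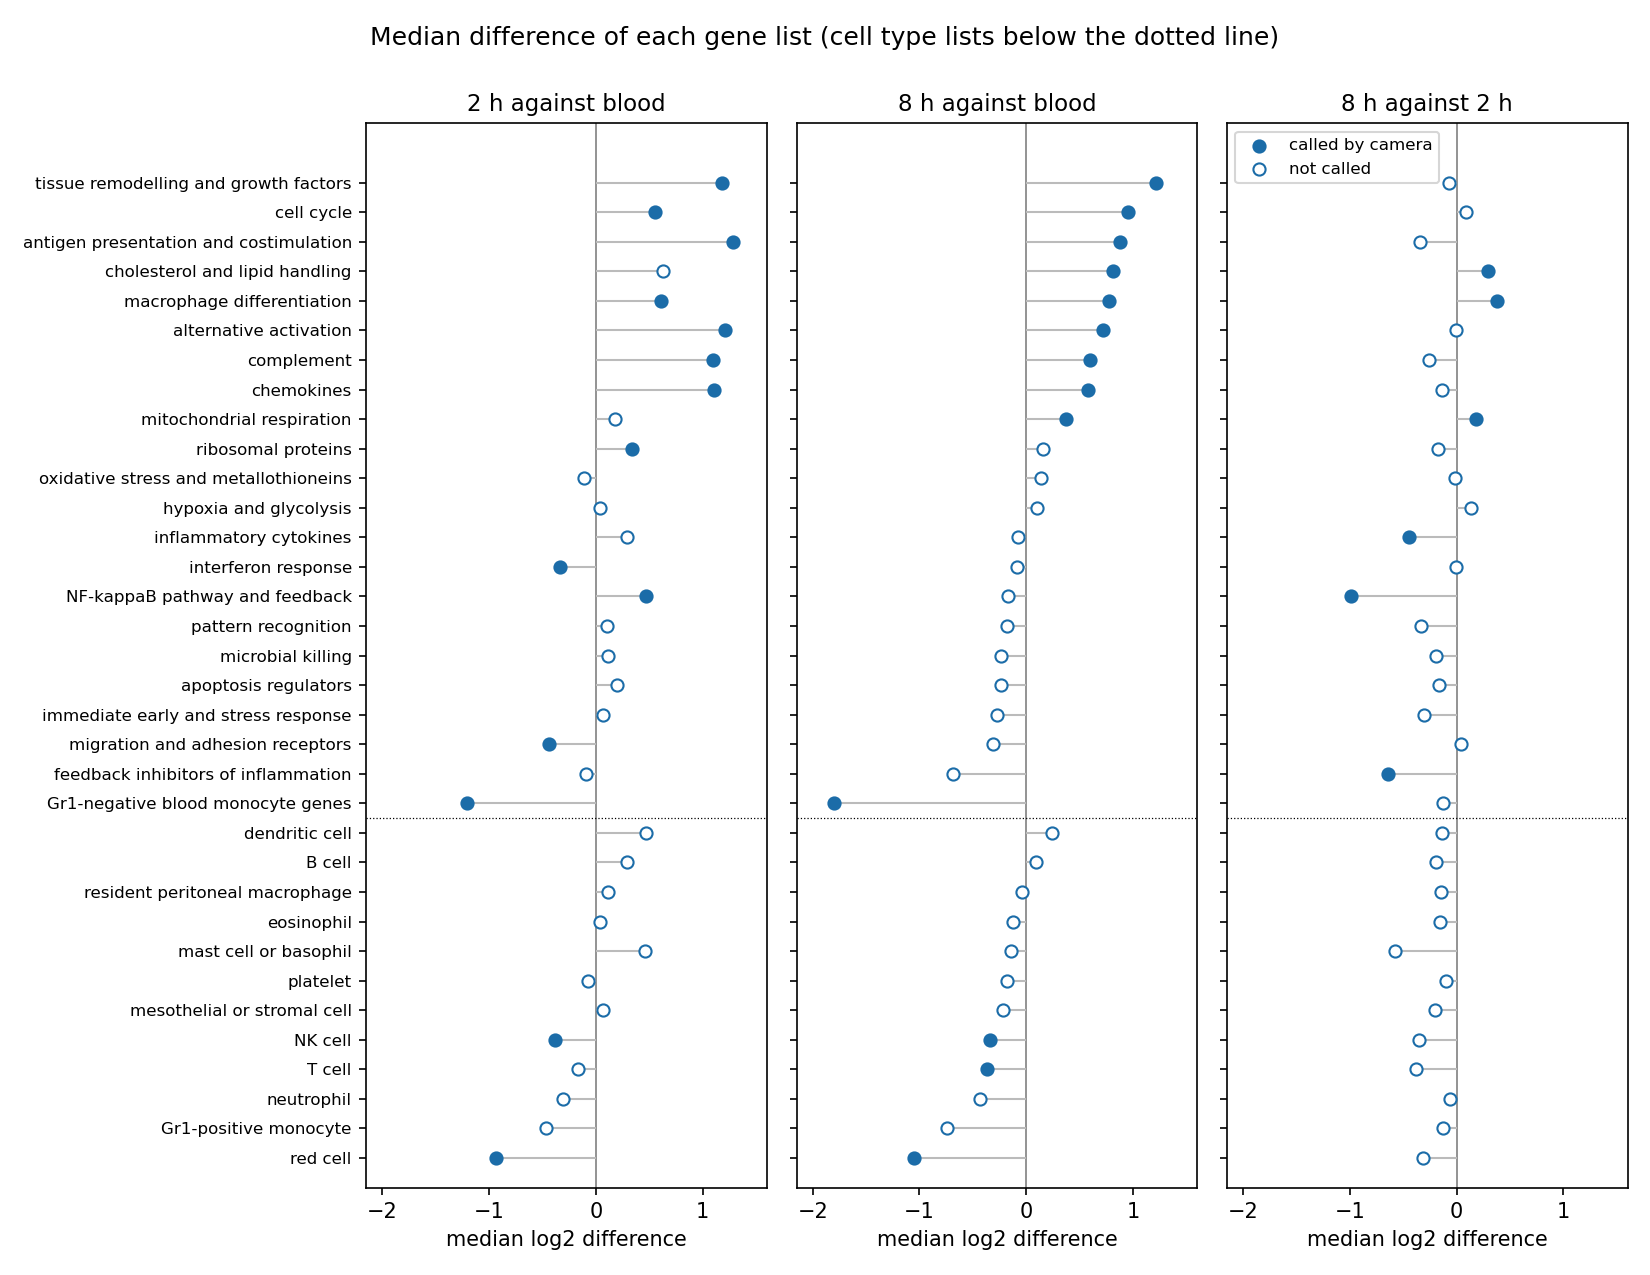
Median log2 difference (x axis) of the tested genes of each of the 34 lists (y axis) in the 3 comparisons; filled points are lists called by camera with its preset correlation, open points are not called. Tissue remodelling and growth factors stood at 1.18 at 2 h and 1.22 at 8 h against blood, the Gr1-negative blood monocyte genes at -1.21 and -1.80, and the NF-kappaB list at -0.99 between 8 h and 2 h.

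The third comparison asks what changes in the peritoneal cells between 2 h and 8 h after infection, where tissue does not differ. As a group, NF-kappaB pathway and feedback genes were lower at 8 h by camera (adjusted p = 8.7e-07), but not with an estimated correlation (adjusted p = 0.328). Their median was -0.99 over 25 genes, 22 of them with a negative difference, and 0 were called by limma, with 1 higher and 11 lower at an unadjusted p under 0.05. Cd83 differed by -2.86 ± 0.38 (adjusted p = 0.136) and Icam1 by -1.78 ± 0.39 (adjusted p = 0.299). Inflammatory cytokine genes were lower by camera (adjusted p = 0.00392), but not with an estimated correlation (adjusted p = 0.194). They had a median of -0.44 over 24 genes, with 0 called by limma and 0 higher and 5 lower at an unadjusted p under 0.05, among them Il1b at -1.51 ± 0.30 (adjusted p = 0.269) and Tnf at -1.64 ± 0.69 (adjusted p = 0.484). Cholesterol and lipid handling genes were higher by camera (adjusted p = 0.00209), but not with an estimated correlation (adjusted p = 0.194). Their median was 0.29 over 22 genes, 16 of them with a positive difference, with 0 called by limma and 3 higher and 0 lower at an unadjusted p under 0.05, led by Scd2, a fatty acid desaturase, at 3.32 ± 0.37 (adjusted p = 0.0562). The tests of single genes called few: 3 genes were higher and 1 lower at 8 h, against 990 and 1515 at an unadjusted p under 0.05. The median over all genes was -0.13.

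Adjusted over the list alone, 1 gene was higher and 9 were lower in the NF-kappaB list, 0 and 2 in the inflammatory cytokine list, and 3 and 0 in the lipid handling list. Feedback inhibitors of inflammation fell (camera adjusted p = 0.0201, and adjusted p = 0.461 with an estimated correlation), with 0 of 20 called by limma, 1 higher and 5 lower at an unadjusted p under 0.05, and 0 and 3 adjusted over the list alone. Il1rn, which belongs to it, stood at -2.11 ± 0.52 (adjusted p = 0.329). Macrophage differentiation genes rose (camera adjusted p = 0.0229, and adjusted p = 0.628 with an estimated correlation), with 0 of 25 called by limma, 5 higher and 0 lower at an unadjusted p under 0.05, and 2 and 0 adjusted over the list alone. Lpl stood at 1.89 ± 0.29 (adjusted p = 0.195). Mitochondrial respiration genes rose (camera adjusted p = 0.00796, and adjusted p = 0.628 with an estimated correlation), with 0 of 28 called by limma, 2 higher and 0 lower at an unadjusted p under 0.05, and 0 and 0 adjusted over the list alone. None of the 12 cell type lists was called between the times (smallest camera adjusted p = 0.0672, for mast cells or basophils), but with scan day as a block that list was called lower (adjusted p = 0.00812).

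Time is partly tied to slide and scan day, so the lists were compared within day 2, where 2 h replicate 3 stood beside the 8 h arrays. With scan day as a block the NF-kappaB median was -1.58 (adjusted p = 6.8e-12), the cytokine median -0.34 (adjusted p = 0.0181), that of feedback inhibitors -0.60 (adjusted p = 0.0167), of lipid handling 0.27 (adjusted p = 0.00492), of macrophage differentiation 0.58 (adjusted p = 0.00045) and of mitochondrial respiration 0.35 (adjusted p = 0.000432). That block also called the interferon response (0.27, adjusted p = 0.00277), remodelling (0.12, adjusted p = 0.00812) and hypoxia and glycolysis (0.32, adjusted p = 0.00992) lists higher. Without 2 h replicate 3, the NF-kappaB median was -0.63, the NF-kappaB, cytokine and lipid handling lists kept their call, and 3 lists were called in place of 6. Feedback inhibitors also lost their call without 8 h replicate 1, and macrophage differentiation and mitochondrial respiration without 8 h replicate 2 or 3, with adjusted p up to 0.161, 0.200 and 0.168. The macrophage differentiation call also ended with slide as a random block (median 0.16 in place of 0.38, adjusted p = 0.0986), and that of feedback inhibitors with array weights and with normexp.

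Ppp1r3e, a subunit that targets a phosphatase to glycogen, was at least 8.95-fold higher at 8 h, with signals below background at 2 h (3.96 ± 0.39, adjusted p = 0.0448). That fold did not hold under normexp background correction, where the difference was -0.0056 (adjusted p = 0.998), or 1.87 without the lowest spots. The other called genes, named after their values were seen, were the clone 4833417J20Rik (3.20 ± 0.32) and the transcript AK048555 (3.01 ± 0.29), both higher, and the transcript AK053814 (-3.71 ± 0.36), each with an adjusted p of 0.0448. AK048555 was below background on all arrays at 2 h and AK053814 on all arrays at 8 h, so the size of these differences is uncertain. Leaving out any 1 array gave 0 or 1 gene higher and 0 to 2 lower, the call of Ppp1r3e ended without each of the 9 arrays in turn (adjusted p up to 0.192), and scan day as a block left 0 higher and 0 lower, with 508 and 728 at an unadjusted p under 0.05.

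**Figure D3:**
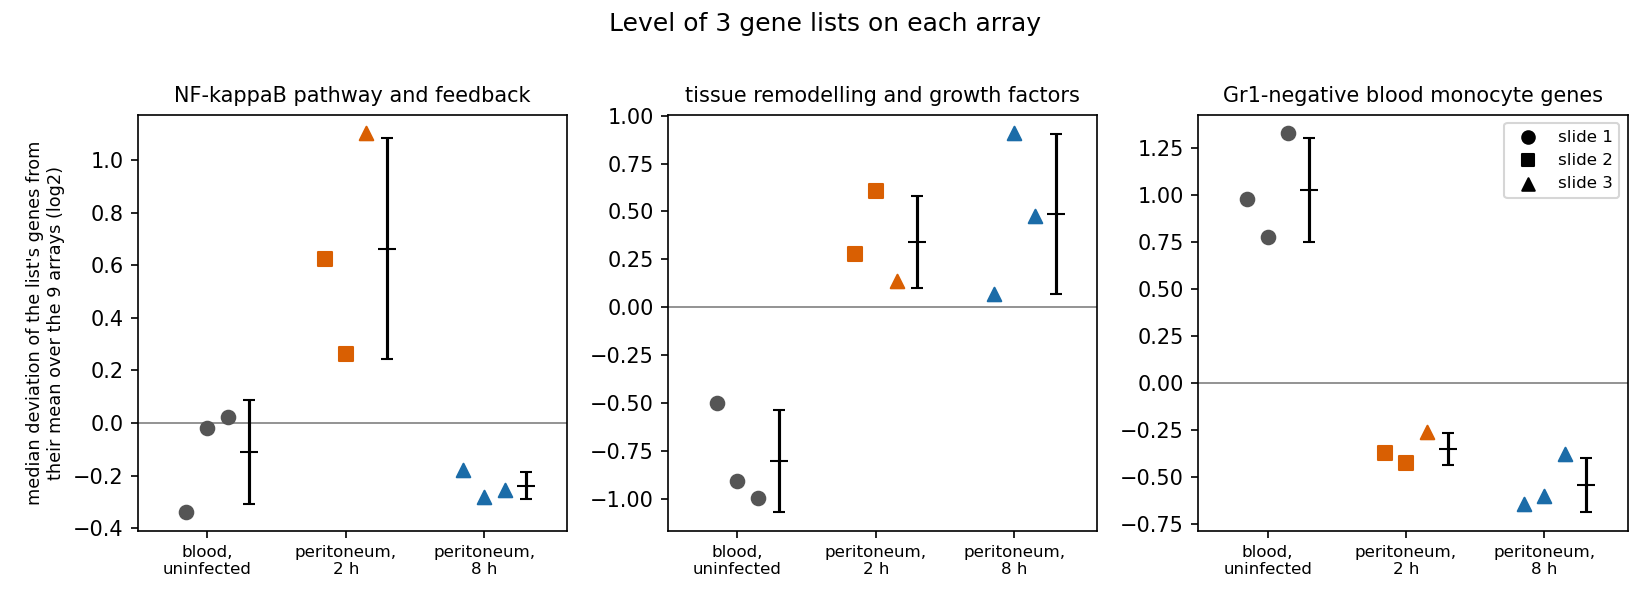
Median deviation (log2, y axis) of the genes of 3 lists from their mean over the 9 arrays, per array, in the 3 groups (x axis); marker shape gives the slide, and bars give the mean ± standard deviation over n = 3 arrays. The NF-kappaB list stood at 0.62, 0.26 and 1.10 on the 2 h arrays, the last on slide 3, and between -0.28 and -0.18 on the 8 h arrays.

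The genes fixed in advance whatever their result showed few other calls. Il4ra, the interleukin-4 receptor chain, rose at 2 h by 1.23 ± 0.25 (adjusted p = 0.0327), a call that ended without any 1 of 8 of the 9 arrays, all but blood replicate 1 (adjusted p up to 0.1003), and differed by 0.84 ± 0.25 at 8 h (adjusted p = 0.124). Spi1, Relb, Nos2, Ccl3, Cxcl2, Flt3, Cx3cr1 and Ly6c1 were not called in any of the 3 comparisons. Maf was not called by its brightest probe, but another kept probe of Maf was called by limma over probes, 2.58 higher at 2 h (adjusted p = 0.0477) and 3.99 higher at 8 h (adjusted p = 0.0142), and yet another 4.41 higher at 8 h (adjusted p = 0.0162). Ly6c1, which encodes a part of the Gr1 epitope family, differed from blood by -2.11 ± 0.59 at 2 h (adjusted p = 0.0797) and by -2.16 ± 0.59 at 8 h (adjusted p = 0.0941). Il6 was not tested, since its signal was not above background on enough arrays, and Relb had 1 usable array at 2 h.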

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

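The tests of slide, scan day, scaling and other cell types as explanations were chosen only after these results were seen, although the quantile and scan-day fits that they use had been planned, as had the counts over other splits of the arrays. A difference between the effects at 8 h and 2 h, by the test of that difference, singled out 4 genes and 6 lists. Between the times, 4 genes passed limma's test: Ppp1r3e (3.96), 4833417J20Rik (3.20) and AK048555 (3.01) were higher at 8 h and AK053814 (-3.71) was lower. Camera, which does not test medians but sets a list's genes against all others, called 6 lists. The lower ones had medians of -0.99 (NF-kappaB pathway and feedback), -0.44 (inflammatory cytokines) and -0.64 (feedback inhibitors of inflammation). Medians of the higher ones were 0.38 (macrophage differentiation), 0.29 (cholesterol and lipid handling) and 0.18 (mitochondrial respiration), beside -0.13 over all genes. None of these list calls held with an estimated correlation, where 3 lists had an unadjusted p under 0.05 and 0 an adjusted one.

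The 6 arrays of each pair of groups make only 10 splits, too few for a share under 0.05. The real split, as the only 1 of 10 with that many, called 1315 genes for 2 h against blood (highest other split 2), 843 for 8 h against blood (highest other 1) and 4 for 8 h against 2 h (highest other 1). Over all 9 arrays, 1 of 100 splits into 3 groups of 3, the real one, called as many as 925 genes. That share is the smallest possible here, since the real split is among the 100, and it makes chance an unlikely source of that count. The highest of the other drawn splits called 558. These splits exchange the arrays freely, while slide and scan day follow the groups, so they do not separate the groups from slide or scan day, and with scan day as a block 205 genes differed.

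The first pattern weighed is the lower NF-kappaB list at 8 h than at 2 h. For the scaling of the arrays, under quantile normalization the list's median was -0.96, against -0.99 before, and it stayed called. That fit moved the median over all genes between the times only from -0.13 to -0.10, so it could hardly have ended the call. It shows only that a shift of all genes of that size is not the source of the list's difference. Slide and scan day stay open. With scan day as a block the median was -1.58 and called, so 2 h replicate 3 did not lie with the 8 h arrays of its slide, but that rests on this 1 array. Without 2 h replicate 3 the median was -0.63 and still called. The 2 h arrays left there were on another slide than the 8 h arrays, so in that fit slide and time cannot be told apart. The time after infection stays among the open explanations and was not tested apart from these.

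The second pattern is the rise of alternative activation, complement and remodelling genes in the peritoneal cells, which resident peritoneal macrophages in the gate could bring, although the gate took F4/80-low cells. Of 17 tested marker genes of these macrophages, 1 was called higher at 2 h and 1 at 8 h, in each case Fn1, which is also on the remodelling list. Others went both ways: Cd9 was called lower at 2 h (-3.47), while Timd4, above background on 1 of 3 blood arrays, differed by 2.31 at 2 h and 4.01 at 8 h (3.05 with the others set to the lowest signal above background) and was not called (adjusted p = 0.217 and 0.0730). Of the list's genes with the brightest signal, which also depends on the probe, Fn1 stood at 0.73, 4.45 and 4.31 (log2) in blood, 2 h and 8 h cells, C4b, also in the complement list, at 1.57, 2.67 and 2.17, and Adgre1, which encodes F4/80, at 2.34, 1.98 and 1.62. Such cells and a change in the monocytes cannot be told apart, because 16 of the 17 genes were above background in blood and 8 are also on another list, while the move into the peritoneal cavity and the infection, which the design changes together, stay open and untested.

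The third pattern is the lower level of Gzma and Gzmb in the peritoneal cells, which NK cells in the blood sort might explain, although the gate removed NK1.1-positive cells. Of the 12 other tested NK cell genes, 0 were called lower at 2 h by limma (adjusted over the list alone, 4 NK cell genes were lower, Gzma included, as at an unadjusted p under 0.05) and 1 at 8 h, Ccl5, a call that ended without 8 h replicate 1 or 2 (adjusted p up to 0.0716). The other kept probe of Ccl5 differed by -2.25 at 2 h (adjusted p = 0.137) and by -4.32 at 8 h (adjusted p = 0.0256), by limma over probes. Other values go with NK cells: adjusted over the list alone, 5 NK cell genes were lower and 1 higher at 8 h, and camera called the list lower at 2 h (adjusted p = 0.0465) and 8 h (adjusted p = 0.00471), but not with an estimated correlation (adjusted p = 0.364 and 0.155). Those of the list with the brightest signal, which also depends on the probe, stood at 3.01, 2.34 and 1.57 (Ccl5), 0.30, 0.53 and 0.17 (Klrd1) and 0.61, 0.23 and 0.09 (Klra8) in blood, 2 h and 8 h cells. Since 13 of the 13 genes tested were above background in blood, 1 (Ccl5) is also on the chemokine list and Gzmb is not on the NK cell list, NK cells and a change in the monocytes cannot be told apart.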

How the results depend on the processing

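Fits with outlier-flagged spots kept and with normexp without the lowest spots were chosen only after the data were seen, while the other alternatives were planned. Of the values of named genes, 2639 kept their direction and side of the threshold under alternatives other than leaving out an array, 250 fell short of it, 36 passed it and 24 changed sign. Leaving out an array, 1214 kept both, 320 fell short, 6 passed and 23 changed sign. Of the values of called lists, 484 kept both, 77 fell short and 0 changed sign (259, 38 and 0 leaving out an array). Signal over background, 13.4 to 17.7 at the median spot, limits what dim genes can show. Where nothing else is said, the cause was not tested.

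Leaving out each array in turn, with the lone loss from a group of 3 borne by the shared spread, gave 214 to 830 genes higher and 205 to 489 lower at 2 h against blood, 139 to 492 and 103 to 339 at 8 h against blood, and 0 to 1 and 0 to 2 at 8 h against 2 h. It gave 404 to 694 genes among the 3 groups, 187 to 542 shared calls, and 9 to 14, 13 to 15 and 3 to 8 called lists at 2 h against blood, 8 h against blood and 8 h against 2 h. Fewer arrays leave less power, by construction, but some counts grew. Without blood replicate 1, 830 genes were higher at 2 h, against 740 with all arrays. Without blood replicate 3, 492 were higher at 8 h against blood, against 483 with all arrays. List calls at 2 h numbered 9 without 8 h replicate 3, and those between the times 3 without 2 h replicate 3.

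Normexp background correction gave 164 genes higher and 150 lower at 2 h, 202 and 152 at 8 h, 0 and 0 between the times, 265 among the groups, 179 shared and 10 lists between the times. It fitted a background mean of -145.7, -290.1, -888.8 and -192.8 on 4 arrays, against -18.3 to -12.6 on the others, where spots lay far below their local background (lowest -65170). Without the lowest spots, counts against blood were 725 and 652 at 2 h and 601 and 511 at 8 h, with 1 and 0 between the times. Fits of only the 6 arrays compared, which have fewer degrees of freedom, gave 253 and 265, 239 and 181, 0 and 0, and 196 shared.

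The replicate number as a block gave 335 and 321, 243 and 163, 0 and 0, 381 among the groups, 280 shared and 8 lists at 2 h. Different mice were used at each time, and the deviations of arrays with the same number correlated at -0.103 to 0.129 across genes, against -0.129 to 0.109 for other pairs, so the numbers do not pair the arrays. Slide as a random block gave 2358 and 1520, 2230 and 1840, 7 and 3, 4598 among the groups and 2121 shared, with an estimated correlation within slides of -0.196, below 0. Scan day as a block gave 276 and 318, 16 and 9, 0 and 0, 205 among the groups, 25 shared and 10 lists between the times, and by construction it ties 8 h to blood through a single array. Array weights gave 1195 higher at 2 h, 1012 and 720 at 8 h, 6 and 2 between the times, 1661 among the groups and 984 shared.

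Between the times, 0 genes were higher and 0 lower with each array's median, without a filter on dim probes and with a mean-variance trend, and 2 were lower with the percentile over probes above background on all arrays and with the strict filter. Lists called at 2 h numbered 9 with each array's median, with the deposited value table and with outlier-flagged spots kept. With an estimated correlation, 0, 0 and 0 lists were called by camera, against 7, 10 and 3 at an unadjusted p under 0.05.

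Sign changes concerned genes that were not called, except Ppp1r3e (8 h against 2 h, -0.0056) and Ccr1 (8 h against blood, -0.30), both under normexp. Under quantile normalization Ccl3 and Nos2 at 2 h were -0.11 and -0.072, and Maf and Retnla between the times -0.0047 and 0.094. Under normexp Ccl3 and Cxcl2 at 8 h against blood were -0.84 and -0.78, and Ccl3 between the times -1.72. With the mean of probes Ifi44 and Cx3cr1 at 2 h were -0.92 and 0.085. The replicate block gave Relb 0.28 and the slide block Flt3 0.067 between the times. The scan day block gave Nos2 at 2 h -0.11, Cxcl2 at 8 h -2.10, and Maf and Ly6c1 between the times -0.070 and 0.40. Array weights gave Tnf, Maf and Relb at 8 h against blood 0.12, -0.059 and 0.089, and Maf, Relb and Ly6c1 between the times -0.061, 0.24 and 0.22. Keeping flagged spots gave Relb 0.67 at 2 h. Leaving out arrays gave, at 2 h, Relb -0.35 to 0.084, Ccl3 -0.72 to 1.21, Nos2 -0.18 to 0.38 and Maf -0.0057 to 0.22. At 8 h against blood it gave Relb -0.58 to 0.27, Spi1 -0.010 to 0.27, Tnf -1.01 to 0.21 and Maf -0.016 to 0.24. Between the times it gave Ccl3 -0.24 to 1.69, Retnla -0.35 to 0.14, Maf -0.14 to 0.11, Ly6c1 -0.53 to 0.45, Flt3 -0.35 to 0.22 and Relb -0.45 to 0.41.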

Other observations

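Several gene groups outside the calls above held single genes with large changes. In the pattern recognition list (4 of 26 higher and 1 lower at 2 h, 3 and 3 at 8 h, 9 and 3, and 4 and 3, adjusted over the list alone, camera adjusted p = 0.231 and 0.659), Msr1, the scavenger receptor A of macrophages, rose by 4.42 ± 0.29 at 2 h and 3.99 ± 0.29 at 8 h. Among immediate early and stress response genes (4 of 26 higher and 3 lower at 2 h, 3 and 4 at 8 h, 5 and 7, and 3 and 7, adjusted over the list alone, camera adjusted p = 0.393 and 0.218), Egr1 rose by 2.95 ± 0.41 at 2 h while Dusp1, a phosphatase that curbs MAP kinases, fell by 2.56 ± 0.18 at 2 h and fell by 3.08 ± 0.20 at 8 h (n = 2 arrays). Egr1 was still 2.61 higher than in blood at 8 h (adjusted p = 0.0177 by limma over probes). Gsr, the glutathione reductase, fell by 3.01 ± 0.36 at 2 h and fell by 2.89 ± 0.40 at 8 h (n = 2 arrays), in a list of oxidative stress and metallothionein genes that was otherwise not called (0 of 17 higher and 1 lower at each time and in each count adjusted over the list alone, camera adjusted p = 0.583 and 0.911). Feedback inhibitors were not called against blood (3 of 20 higher and 4 lower at 2 h, 1 and 3 at 8 h, camera adjusted p = 0.802 and 0.0534), nor were lipid handling genes at 2 h (5 of 22 higher, 2 lower, 7 and 3 adjusted over the list alone, camera adjusted p = 0.231), where Abcg1, a cholesterol exporter, fell by 3.09 ± 0.46. Microbial killing (1 of 21 higher, 2 lower at 2 h), hypoxia and glycolysis (0 of 24 higher, 1 lower) and apoptosis regulators (1 of 21 higher, 0 lower) had camera adjusted p of 0.867, 0.587 and 0.587 at 2 h and of 0.201, 0.533 and 0.249 at 8 h.

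Markers of other cell types, apart from those of red, T and NK cells, were not called as lists against blood at either time. At 2 h the counts higher and lower were 3 and 1 of 12 Gr1-positive monocyte genes, 0 and 2 of 10 eosinophil genes, 1 and 0 of 13 dendritic cell genes and 0 and 2 of 19 T cell genes (camera adjusted p = 0.802, 0.647, 0.975 and 0.0989). Fn1, a matrix protein gene that is also on the resident macrophage, Gr1-positive monocyte and remodelling lists, rose by 3.72 ± 0.36 at 2 h and 3.58 ± 0.36 at 8 h, while Plac8 fell by 3.15 ± 0.43 at 8 h. By limma, 0 genes were called at 2 h in the neutrophil, B cell, mast cell or basophil, mesothelial or stromal cell and platelet lists (camera adjusted p = 0.0989, 0.583, 0.583, 0.791 and 0.381), with 0, 2, 2, 0 and 1 higher and 4, 1, 0, 0 and 2 lower at an unadjusted p under 0.05. With scan day as a block, the neutrophil list was called lower at 8 h (median -0.51, adjusted p = 0.0180). Without it, at 8 h the camera adjusted p of these 5 lists were 0.0683, 0.890, 0.399, 0.117 and 0.417, and those of the Gr1-positive monocyte, eosinophil and dendritic cell lists 0.842, 0.417 and 0.659.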
